A study of Mus musculus with 6 samples.

How the data were processed

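The series holds 6 RNA sequencing libraries of sorted Foxp3+ iTreg from C57BL/6 mice that carry a Foxp3-DTR/EGFP reporter, 3 with vehicle (DMSO) and 3 with 100 nM PGE2 for 6 h. Per the labels' protocols, RNA was extracted with a column kit for small samples and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. Tumour-infiltrating cells and natural regulatory T cells named in the series' design text were not analysed here. Groups and replicate numbers were taken from the sample titles.

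Per the submitters' processing notes, Trim Galore and HISAT2 were used on the mouse build mm10; their versions, the annotation and the program that made the gene tables are not given in the sources used here. Each library has a gene table which, per the file headers, gives each gene's position with its coverage, FPKM and TPM. The deposited FPKM is scaled by the authors to library size and transcript length, and the deposited coverage is the mean read depth over the gene. The deposited TPM column was treated as a score, because each table lists a locus both as an assembled locus and under its annotated gene, so that the column sums to 1.91 to 1.94 times the sum of the assembled loci alone. These sum to 1000000, and annotated genes reach 91.4% to 94.2% of that. The files held FPKM where counts had been planned for, so a count model was not used and the test set out for normalized values was applied. Whole reads could not be recovered, because the values rest on coverage. The ratio of coverage to FPKM was within 1% of one constant per library for 97.4% to 97.9% of 2165 to 2295 genes with a single transcript, and this constant, 3.996 to 5.446 gigabases of fragments, served as depth. The median coverage of genes over 1 FPKM was 27.6 to 36.1. No interval for counting error was computed, since counts are not at hand.

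Only entries under an annotated gene were used. Of 47643 gene IDs, 47224 are in GENCODE release M21 (GRCm38, the mm10 assembly) without regard to version. With the version, 39106 matched, and 100% of these had the same start and end. IDs listed more than once in a table, 21 to 27 per library, were summed. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 12113 in all, of which 10047 are annotated as protein coding and 7 are listed at 0 in at least 1 library. For tested genes that overlap an assembled locus, the annotated FPKM was set against that of the locus. It was over 80% of the locus value for 82.4% to 84% of them per library, and under 50% for 7.6% to 8.3%. A locus shared by several genes was counted for each of them. Values were used as log2(FPKM + 1), so a fold change understates the change of low genes.

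PGE2 was compared with vehicle by limma (version 3.58.1 in R 4.3.3) with a moderated variance that follows the mean level, all 6 libraries, no covariate and Benjamini-Hochberg adjustment over the tested genes. Tests were two-sided with a threshold of 0.05. For 25 gene lists fixed before the data were examined, the 20 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and adjusted over these 20 lists. Because that preset can overstate the evidence, the same test with an estimated correlation is given beside each call, and no list passed it. The remaining lists (Th17, myeloid, NK and CD8, erythroid and platelet, stromal and endothelial) are given as levels. Library composition was compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

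Genes named in the text follow a rule fixed before the data were examined. It takes Foxp3, Il2ra, Ptger2 and Ptger4, and the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 FPKM in the higher group and no overlap between groups, leaving out unnamed gene models, pseudogenes and IDs without a symbol. From each fixed list it takes up to 4 called members with the smallest p or, where none was called, the member with the highest level; all called members of the tumour-infiltrating Treg and cAMP lists may be named. Ptger1 and Ptger3 among the receptors, Lyz2 and Klrd1 among the markers, and genes named in the closing part on other observations, were chosen after their values were seen.

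The procedure was tested on simulated data for the comparison of PGE2 with vehicle, with 12113 genes at the observed levels and spread. It recovered 30% of 100 genes changed 1.5-fold and 70% of 100 genes changed 2-fold, with 5 false calls, 4.8% of all calls, and it made 0 calls when no gene was changed. Of random lists, 2% had a p under 0.05. The simulated genes were drawn independently of each other and without a replicate-number effect. The simulation therefore does not show how the tests behave when genes move together. In the fixed lists the estimated correlation reached 0.67.

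Whether the replicate numbers pair the samples was checked from the titles' numbers and the values. The deviations from the group means correlated across genes at 0.23 for the libraries numbered 1, 0.31 for those numbered 2 and 0.53 for those numbered 3, all over 0.1, and the number 3 libraries stood apart in both groups. Vehicle replicate 2 and PGE2 replicate 1 also correlated, at 0.27, and vehicle replicate 1 and PGE2 replicate 2 at 0.15. Deviations within a group of 3 sum to 0, so number 3 libraries that deviate alike can alone push these values above 0. The check therefore does not show that numbers 1 and 2 pair samples. Any pairing is read from these values, since the labels do not say what a number stands for. A fit with the number as a block was set as an alternative before the data were examined. It is given beside each result whose call or count it changes.

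Alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, a filter of at least 1 FPKM in 3 or more libraries, median-of-ratios scaling, scaling to the total of annotated FPKM, a test against a fold of 1.5, the replicate block, each library left out in turn and, for lists, an estimated correlation and fry. Those chosen after the data were seen were gene coverage scaled to depth in place of FPKM, the FPKM of the assembled locus for 10124 genes with a locus of their own, library weights estimated from the data, and both number 3 libraries left out. In all-gene terms the scalings moved the median log2 change from -0.028 to 0.001 and -0.065.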

Results

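Gene expression was measured by RNA sequencing in induced regulatory T cells (iTreg) of the mouse. Splenic CD4+ T cells carrying an EGFP reporter for Foxp3, the transcription factor that defines regulatory T cells, were cultured for 2 days with antibodies to CD3 and CD28 and with TGF-β. The cells then received vehicle or 100 nM prostaglandin E2 (PGE2), a lipid mediator sensed by the receptors EP1 to EP4, for 6 h, and the Foxp3+ cells were sorted on the reporter. There were 3 libraries with vehicle and 3 with PGE2. The comparison asks which transcripts differ in Foxp3+ iTreg after PGE2, and the title of the series ties it to EP2 and EP4 signalling and to the phenotype of regulatory T cells in tumours. Values are FPKM (fragments per kilobase of transcript, scaled to library size). Depth was read from the ratio of coverage to FPKM, and was 5.121, 5.045 and 3.996 gigabases of fragments in vehicle replicates 1, 2 and 3 and 5.446, 5.195 and 4.542 in PGE2 replicates 1, 2 and 3. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples.

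After 6 h of PGE2, of 12113 tested genes, 69 rose and 29 fell. Ramp3, a protein that modifies the ligand preference of the calcitonin-like receptor, rose from 2.97 ± 1.08 to 30.8 ± 2.49 FPKM (SD, n = 3; 8.22-fold on the log2(FPKM + 1) scale, log2 change 3.04, SE 0.21, adjusted p = 0.002 with limma). Plaur, the urokinase receptor, rose 4.35-fold from 1.81 ± 0.35 to 11.2 ± 0.276 FPKM, and Dgat1, the enzyme of the last step of triacylglycerol synthesis, rose 3.87-fold from 28.7 ± 8.31 to 112 ± 18.7 FPKM. Tgm2, a transglutaminase, rose from 10.8 ± 2.61 to 39.1 ± 5.04 FPKM, and Sema4c, a semaphorin, from 0.61 ± 0.0691 to 4.03 ± 0.106 FPKM. Il12rb2, a chain of the IL-12 receptor, rose 2.73-fold to 37.2 ± 3.37 FPKM.

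The other genes among the 12 largest rises were Crem, Nr4a3 and Fosl2, described with the cAMP group, and Cables1, Atp1b1 and Pja1. Cables1 rose by a log2 change of 1.43 (SE 0.11), Atp1b1, the beta subunit of the sodium pump, by 1.32 (SE 0.13), and Pja1, a ubiquitin ligase, by 1.3 (SE 0.09). In the mm10 coordinates of the files, Ramp3 (ENSMUSG00000041046.7) lies on chromosome 11 from 6658521 to 6677475, Plaur (ENSMUSG00000046223.10) on chromosome 7 from 24462484 to 24475968, and Crem (ENSMUSG00000063889.16) on chromosome 18 from 3266048 to 3337748. Each is annotated as a protein-coding gene, and the value is that of the whole gene. The 2 groups did not overlap for any of the 98 called genes, nor for 19.7% of all tested genes, where chance with 3 libraries against 3 gives 10%.

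Foxp3 (ENSMUSG00000039521.12, chromosome X from 7579676 to 7595243) stood at 92.1 ± 14.4 FPKM with vehicle and 115 ± 22.5 with PGE2 (SD, n = 3), a difference that did not pass the test (log2 change 0.32, SE 0.17, adjusted p = 0.51 with limma). Il2ra, the alpha chain of the IL-2 receptor, was at 691 ± 59.6 and 640 ± 27.6 FPKM (adjusted p = 0.75). Ptger4 (ENSMUSG00000039942.15, chromosome 15 from 5206661 to 5244187), which encodes EP4, was at 31.9, 23.9 and 22.1 FPKM in vehicle replicates 1, 2 and 3 and at 17.6, 14.9 and 14.5 in PGE2 replicates 1, 2 and 3. Its log2 change of -0.68 (SE 0.15) missed the threshold at adjusted p = 0.1, and passed it with the replicate number as a block (adjusted p = 0.015, with a range of 0.0046 to 0.31 over the alternatives that test against no change). Ptger2, which encodes EP2, was lower, at 3.29 ± 0.0466 FPKM with vehicle and 3.55 ± 0.303 with PGE2 (adjusted p = 0.81). Ptger1, which encodes EP1, was at 25 ± 1.58 FPKM with vehicle and 23.6 ± 2.74 with PGE2 (adjusted p = 0.83 with limma). Ptger3, which encodes EP3, was under 1 FPKM in both groups. Of 6 tested genes for PGE2 receptors and prostanoid handling, 0 rose and 0 fell by limma; 1, Ptger4, was lower at an unadjusted p under 0.05, and it fell when adjusted over the list alone and with the block. The highest of the 6 was Ptges3, at 65.4 ± 10.8 and 56.8 ± 7.4 FPKM. As a list they had a median log2 change of -0.17 (adjusted p = 0.1 with camera), which passed with the replicate block (adjusted p = 0.048, with a range of 0.038 to 0.42 over the alternatives). With the block and an estimated correlation the list gave adjusted p = 0.43.

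**Figure D1:**
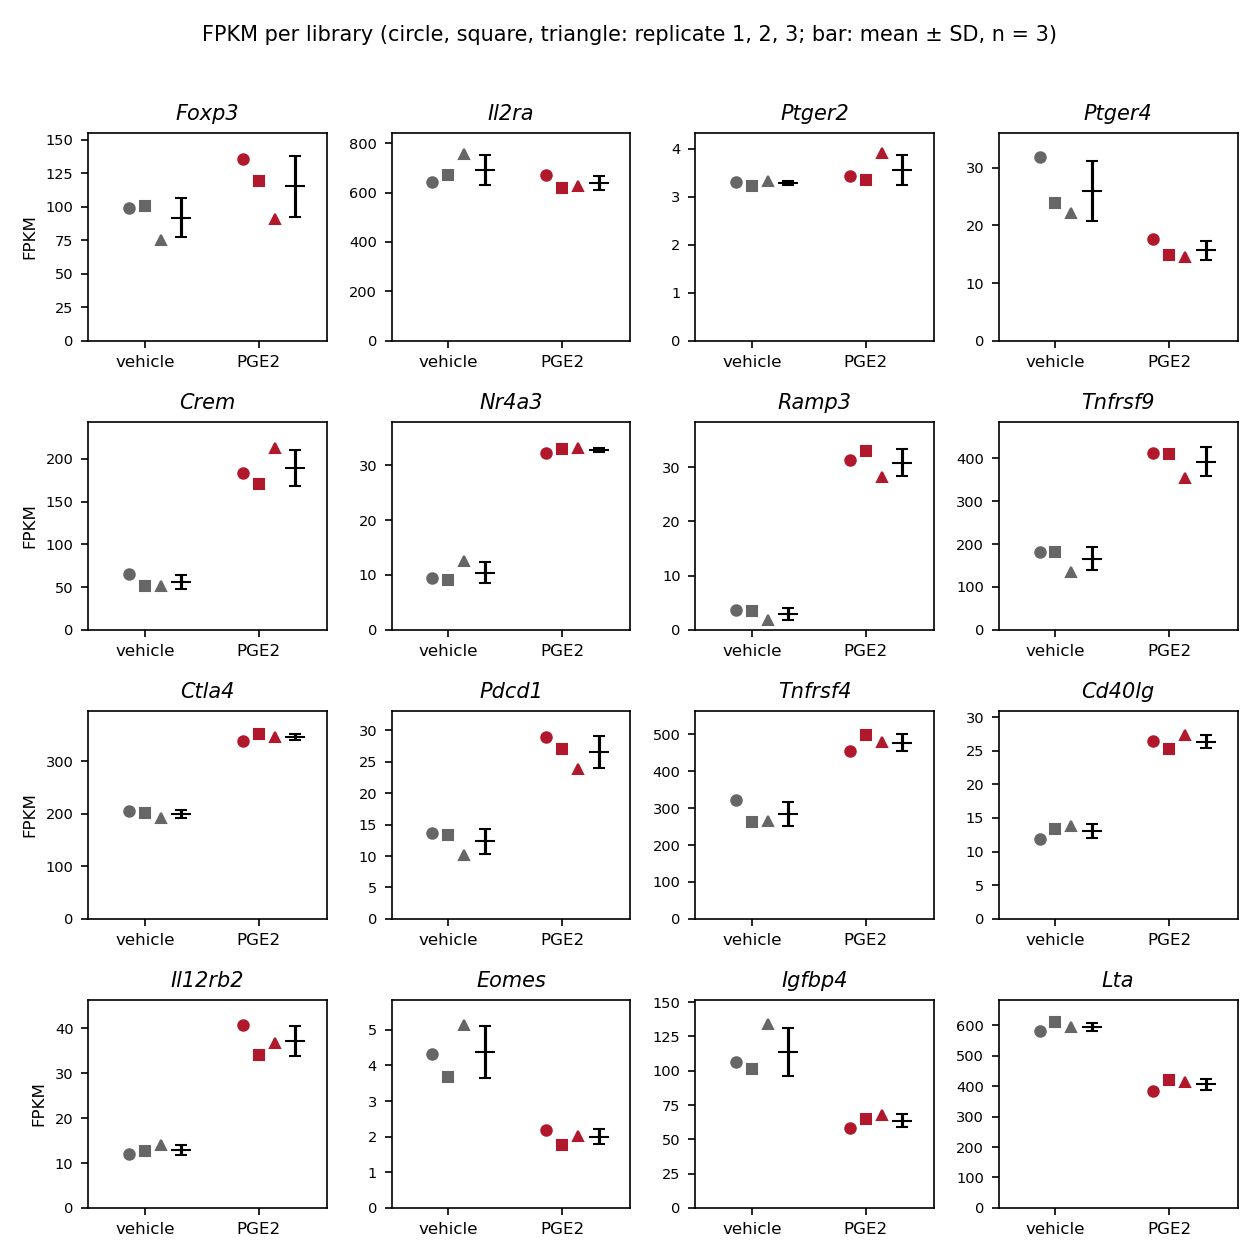
FPKM of 16 named genes in each library, with vehicle in grey and PGE2 in red; circles, squares and triangles are replicates 1, 2 and 3, bars are the mean ± SD of 3 libraries, and each vertical axis starts at 0. Crem and Ramp3 are higher in each PGE2 library than in any vehicle library, whereas Foxp3 and Il2ra overlap between the groups.

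On the log2(FPKM + 1) scale 3 of the 29 falls were at least 2-fold, against 24 of the 69 rises. These 3 were Tmcc1, Zfp710 and Traj57, and the falls of Tmcc1 and Zfp710 were not seen in read coverage. Eomes, a T-box factor of cytotoxic and memory T cells, fell from 4.38 ± 0.729 to 2 ± 0.217 FPKM (log2 change -0.84, SE 0.13, adjusted p = 0.046 with limma). Lair1, an inhibitory receptor for collagen, fell from 4.37 ± 0.311 to 2.02 ± 0.434 FPKM, and Igfbp4, which binds insulin-like growth factors, from 114 ± 17.5 to 63.6 ± 4.92 FPKM. Aen, an exonuclease induced by p53, fell from 20.2 ± 0.288 to 11.3 ± 1.61 FPKM. Lad1, a basement membrane protein, fell by 0.92 on the log2 scale, Nov, a secreted matricellular protein, by 0.73, and Pus7, a pseudouridine synthase, by 0.71. Traj57, a joining segment of the T cell receptor alpha locus, fell from 3.82 ± 0.264 to 0.364 ± 0.234 FPKM. It is annotated over a short span, chromosome 14 from 54158505 to 54158569, and had no assembled-locus value. The other falls among the largest 12 were Tmcc1, Zfp710, Sys1 and R3hdm1, and they were not seen in the read coverage of the gene. Tmcc1 went from 85.2 ± 22.3 to 6.34 ± 1.86 FPKM (log2 change -3.55, SE 0.22), while the log2 change of its coverage was 0.23 (SE 0.25). The log2 change of Zfp710 was -1.71 in FPKM and 0.01 in coverage (SE 0.1), that of Sys1 -0.77 and 0.09, and that of R3hdm1 -0.72 and -0.16. For the other 94 of the 98 called genes the change in coverage kept its sign and was at least 50% of the change in FPKM.

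**Figure D2:**
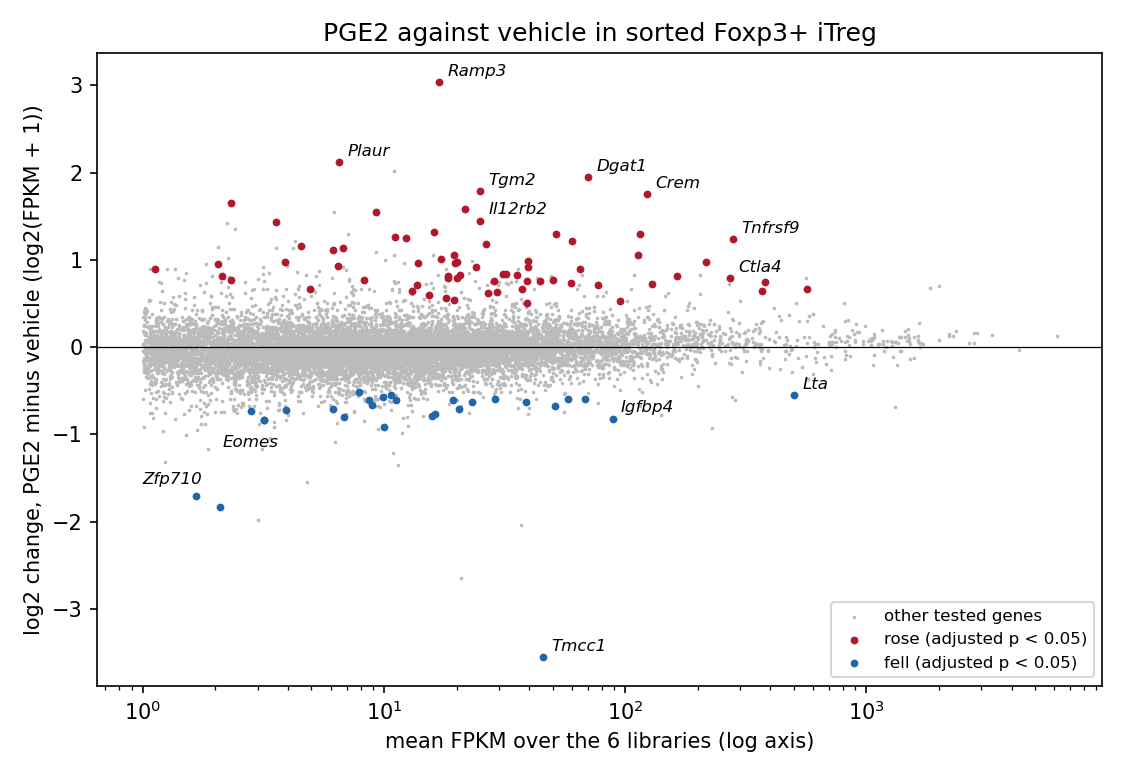
Log2 change of each of the 12113 tested genes, PGE2 minus vehicle on log2(FPKM + 1), against its mean FPKM over the 6 libraries on a log axis; red points are the 69 genes that rose and blue points the 29 that fell. Rises reach 3.04 (Ramp3), and the lowest point, Tmcc1 at -3.55, is a fall in FPKM that its coverage does not share.

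The counts moved with the libraries and with the block. With the replicate number as a block, 215 genes rose and 180 fell, and these held all 98 genes called without it. Without vehicle replicate 1, 36 rose and 4 fell; without vehicle replicate 2, 29 and 4; without vehicle replicate 3, 53 and 16. Without PGE2 replicate 1, 28 rose and 7 fell; without PGE2 replicate 2, 16 and 6; without PGE2 replicate 3, 47 and 6. All 98 genes kept their sign in each of these fits, 18 passed in all 6, and 33 passed in none. Ramp3, Plaur, Crem, Sema4c, Nr4a3, Fosl2, Il12rb2, Cables1, Pja1, Cd40lg and Traj57 passed in all 6, whereas Lad1, Lair1, Eomes, Nov, R3hdm1, Pus7, Lta and Il7r passed in none. Atp1b1 missed the threshold without PGE2 replicate 2 (adjusted p = 0.056), Tgm2 without PGE2 replicate 1 (0.051) or 2 (0.056), and Dgat1 without vehicle replicate 2 (0.054) or PGE2 replicate 1 (0.071) or 2 (0.08). Igfbp4 and Sys1 passed only without vehicle replicate 3, and Aen only without PGE2 replicate 1, with adjusted p in the other fits of up to 0.17, 0.18 and 0.15.

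Genes that respond to cAMP through CREB, the messenger raised by EP2 and EP4, were higher with PGE2 as a group. Of 21 tested members 4 rose and 0 fell, with 6 rising when adjusted over the list alone and 7 with the replicate block. Crem, a cAMP-responsive modulator of CREB targets, rose 3.36-fold from 55.8 ± 8.3 to 189 ± 21.1 FPKM. Nr4a3, an orphan nuclear receptor, rose 2.98-fold to 32.8 ± 0.451 FPKM, Fosl2, an AP-1 subunit, 2.92-fold to 14.3 ± 1.99 FPKM, and Rgs2, a regulator of G protein signalling, 1.9-fold to 8.71 ± 0.213 FPKM. The median log2 change of the list was 0.32 (adjusted p = 1.3e-10 with camera). With an estimated correlation between members the list gave adjusted p = 0.42, the highest value over its alternatives, which began at 4.3e-13. The median was 0.17 without vehicle replicate 3 and 0.54 without PGE2 replicate 3. Rgs2 passed without vehicle replicate 3 (adjusted p = 0.033) and missed the threshold without each of the other 5 libraries, at adjusted p of up to 0.16.

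Genes known from tumour-infiltrating regulatory T cells rose in part. Of 26 tested members 4 rose and 0 fell, with 8 rising and 1 falling when adjusted over the list alone and 7 rising and 1 falling with the replicate block. Tnfrsf9, the costimulatory receptor 4-1BB, rose 2.37-fold from 166 ± 27 to 393 ± 34.2 FPKM (adjusted p = 0.013 with limma). Pdcd1, the inhibitory receptor PD-1, rose 2.07-fold from 12.4 ± 1.97 to 26.6 ± 2.53 FPKM, Ctla4, an inhibitory receptor of regulatory T cells, 1.73-fold from 199 ± 7.14 to 345 ± 5.93 FPKM, and Tnfrsf4, the costimulatory receptor OX40, 1.69-fold from 284 ± 33.3 to 478 ± 22.1 FPKM. The median log2 change of the list was 0.17 (adjusted p = 4.4e-05 with camera). It gave adjusted p = 0.43 with an estimated correlation, the highest of its alternatives, and 1e-07 was the lowest. The median depended on single libraries: it was 0 without vehicle replicate 3, 0.05 without PGE2 replicate 1, 0.29 without vehicle replicate 1 and 0.32 without PGE2 replicate 3. Ctla4 missed the threshold without vehicle replicate 2 (0.059) or PGE2 replicate 2 (0.074), Tnfrsf9 without PGE2 replicate 1 (0.069) or 2 (0.084), Pdcd1 without vehicle replicate 1 (0.055) or 2 (0.066) or PGE2 replicate 1 (0.099) or 2 (0.11), and Tnfrsf4 without each library but vehicle replicate 1, at up to 0.18.

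Treg identity genes and suppressive effector molecules were higher as groups, each with Ctla4, which all 3 of these lists hold, as the 1 member that rose. The 3 lists share other members too, and most of the tested effector molecules are also in the tumour-infiltrating list. The 3 results are therefore not independent. Of 17 identity genes 0 fell, while 7 rose and 3 fell when adjusted over the list alone and 6 rose and 1 fell with the replicate block. Their median log2 change was 0.27 (adjusted p = 0.0075 with camera), with adjusted p = 0.42 with an estimated correlation and 0.0011 at the lowest of the alternatives. Of 12 suppressive effector molecules 0 fell, and 2 rose both when adjusted over the list alone and with the replicate block. Of the 12 molecules, 8 had a higher mean with PGE2 and 4 a lower one. Their median was 0.12 (adjusted p = 0.029), with adjusted p = 0.43 with an estimated correlation and 0.0018 at the lowest. The identity list missed the threshold without vehicle replicate 3 (0.056) or PGE2 replicate 1 (0.097), and the effector list without vehicle replicate 2 (0.05) or 3 (0.17) or PGE2 replicate 1 (0.13). The identity median was 0.18 without vehicle replicate 3, and the effector median 0.03 without vehicle replicate 2 and 0.18 without vehicle replicate 1.

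Genes of helper lineages and of T cell activation moved singly. In the Th1 list, Il12rb2 rose and Eomes fell among 13 tested members, with 3 rising and 2 falling when adjusted over the list alone and 2 and 2 with the replicate block (median 0.01, adjusted p = 0.18 with camera). Of 6 Th2 genes 0 rose and 0 fell by limma, 1 was higher and 1 lower at an unadjusted p under 0.05 and with the block, and 0 rose and 1 fell when adjusted over the list alone; Il4ra, the highest, was at 105 ± 17.1 and 111 ± 17.3 FPKM. The Th2 list had a median of 0.19 (adjusted p = 0.32), which passed with the replicate block (adjusted p = 0.048, with a range of 0.048 to 0.55) and not with the block and an estimated correlation (adjusted p = 0.43). The Th2 median was 0.01 without vehicle replicate 3 and 0.1 without PGE2 replicate 2, and the Th1 median was 0.2 without vehicle replicate 1, 0.1 without PGE2 replicate 1 and -0.01 without vehicle replicate 2. Of 14 Th17 genes 12 were under 1 FPKM, and Maf was at 13.4 ± 2.58 and 12.8 ± 3.05 FPKM. Of 19 TCR and NF-kB response genes 1 rose and 0 fell: Cd40lg, the ligand of CD40, went from 13 ± 0.983 to 26.3 ± 0.987 FPKM (adjusted p = 0.0057 with limma). Adjusted over the list alone or with the block, 1 rose and 1 fell, and the list median was -0.01 (adjusted p = 0.89); it was -0.2 without vehicle replicate 3 and 0.15 without PGE2 replicate 3, so its direction depends on the libraries. Of 6 cytokine genes of conventional activated CD4 T cells, Cd40lg rose and Lta, lymphotoxin alpha, fell from 595 ± 14.8 to 406 ± 19 FPKM, also when adjusted over the list alone (median -0.14, and -0.09 without PGE2 replicate 1, adjusted p = 0.52).

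Glycolysis genes were higher as a group although no single member passed. Of 19 members 18 had a higher mean with PGE2, 0 rose over all genes by limma, 9 were higher and 1 lower at an unadjusted p under 0.05, and 6 rose and 1 fell when adjusted over the list alone. With the replicate block 2 rose. Ldha, lactate dehydrogenase, was at 903 ± 48.9 FPKM with vehicle and 1070 ± 51.4 with PGE2 (adjusted p = 0.38). The list median was 0.24 (adjusted p = 1e-07 with camera), with adjusted p = 0.42 with an estimated correlation and 2.4e-08 at the lowest of the alternatives. Oxidative phosphorylation genes had a median of 0 over 23 members (adjusted p = 0.44; -0.05 without PGE2 replicate 3 and 0.11 without PGE2 replicate 1), with 0 called over all genes, over the list alone or at an unadjusted p under 0.05; Atp5b, the highest, was at 469 ± 6.56 and 452 ± 17.3 FPKM.

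Interferon-stimulated genes were higher with PGE2 as a group. Of 20 tested members 18 had a higher mean with PGE2, 2 rose and 0 fell, and 8 rose when adjusted over the list alone and 5 with the replicate block. Gbp2, a guanylate-binding protein, rose from 97.1 ± 0.518 to 160 ± 8.9 FPKM (adjusted p = 0.012 with limma), and Irf7, a transcription factor of the interferon response, from 5.85 ± 0.322 to 10.8 ± 1.62 FPKM (adjusted p = 0.045). The median was 0.37 (adjusted p = 1.9e-09 with camera), with adjusted p = 0.4 with an estimated correlation and 1.4e-10 at the lowest of the alternatives. Gbp2 missed the threshold without vehicle replicate 1 (0.06) or 2 (0.078) or PGE2 replicate 2 (0.086), and Irf7 without each library but PGE2 replicate 1, at up to 0.21.

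Of 22 cholesterol synthesis genes 0 were called over all genes or over the list alone, and 1 was higher at an unadjusted p under 0.05. Their median was 0.09 (adjusted p = 0.038 with camera; adjusted p = 0.76 with an estimated correlation, 1e-05 at the lowest), and Fdps, the highest, was at 72.8 ± 14.8 and 92.3 ± 19.9 FPKM. Of 17 unfolded protein and ATF4 response genes 0 were called, 6 were lower and 1 higher at an unadjusted p under 0.05, and 4 fell both when adjusted over the list alone and with the replicate block. Their median was -0.07 (adjusted p = 0.038; 0.51 with an estimated correlation, 0.0034 at the lowest), and Xbp1, the highest, was at 271 ± 15.4 and 284 ± 17.7 FPKM. Of 9 heat shock genes 0 were called, 3 were lower at an unadjusted p under 0.05, 2 fell when adjusted over the list alone and 1 with the block. Their median was -0.11 (adjusted p = 0.038; 0.42 with an estimated correlation, 0.019 at the lowest), and Hspa8, the highest, was at 1340 ± 90.1 and 1240 ± 14.8 FPKM.

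Of 19 trafficking receptors 0 were called over all genes, 6 were higher and 2 lower at an unadjusted p under 0.05, 5 rose and 1 fell when adjusted over the list alone, and 1 rose and 1 fell with the block. Their median was 0.21 (adjusted p = 0.0075 with camera; 0.42 with an estimated correlation, 0.00061 at the lowest), and Selplg, the selectin ligand PSGL-1, was at 349 ± 28.4 and 477 ± 17.4 FPKM (adjusted p = 0.096). The trafficking list missed the threshold without PGE2 replicate 1 (0.12). The cholesterol list passed only without vehicle replicate 3 (1e-05) or PGE2 replicate 1 (0.017), the ATF4 list only without vehicle replicate 3 (0.0034) or PGE2 replicate 2 (0.01), and the heat shock list only without vehicle replicate 2 (0.028) or PGE2 replicate 3 (0.036). Without the other libraries these 3 lists reached adjusted p of up to 0.52, 0.15 and 0.12, and with coverage in place of FPKM they missed it at 0.052, 0.056 and 0.051. The cholesterol median was 0 without vehicle replicate 1, 0.06 without vehicle replicate 2 and 0.14 without vehicle replicate 3, and the heat shock median -0.05 without vehicle replicate 1. The ATF4 median was -0.15, -0.2 and -0.29 without vehicle replicates 1, 2 and 3, and -0.21, -0.2 and -0.12 without PGE2 replicates 1, 2 and 3. With fry, which asks whether the genes of a list move one way without comparing them with other genes, the tumour-infiltrating Treg (0.18), identity (0.17), effector (0.18), cholesterol (0.73), trafficking (0.18) and ATF4 (0.2) lists missed it. Without both number 3 libraries the effector (0.072) and heat shock (0.064) lists missed it.

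Lists tied to quiescence, TGF-β and division were not called. Among 14 naive and memory T cell genes, Il7r, the IL-7 receptor, rose from 15.8 ± 0.257 to 23.4 ± 0.964 FPKM and Igfbp4 fell, with 2 rising and 1 falling when adjusted over the list alone (median 0.16, adjusted p = 0.067 with camera). This list passed with fry (0.038) and with coverage in place of FPKM (0.032), and gave adjusted p = 0.42 with an estimated correlation, the highest of its alternatives. Its median was 0.06 without PGE2 replicate 2 and 0.1 without vehicle replicate 2. Of 15 TGF-β response genes 0 were called, and 1 rose and 1 fell when adjusted over the list alone, as many as at an unadjusted p under 0.05; with the block 1 fell. Id2, the highest, was at 37.4 ± 2.97 and 32.7 ± 1.07 FPKM (list median -0.11, and -0.07 without PGE2 replicate 3, adjusted p = 0.52). Of 30 cell cycle genes 0 were called over all genes, over the list alone or at an unadjusted p under 0.05, and 1 rose with the block. Pcna was at 322 ± 31.4 and 314 ± 36.1 FPKM (list median -0.06, adjusted p = 0.79; 0.05 without vehicle replicate 3 and -0.1 without vehicle replicate 1).

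**Figure D3:**
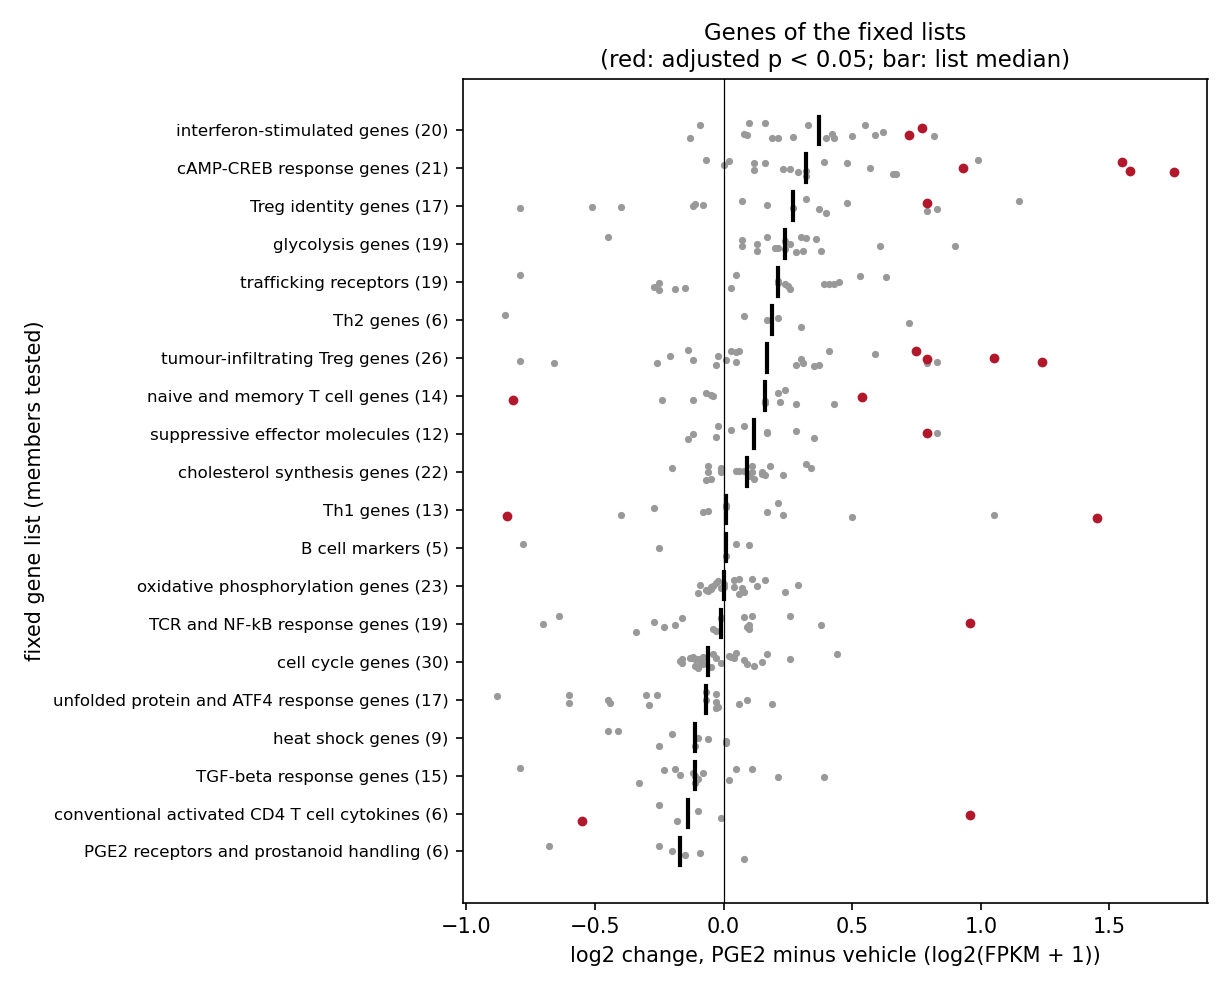
Log2 change, PGE2 minus vehicle on log2(FPKM + 1), of each tested member of the 20 fixed lists with at least 5 tested members; points are genes, red points passed limma over all genes, and black bars are list medians. Medians run from -0.17 for PGE2 receptors and prostanoid handling to 0.37 for interferon-stimulated genes.

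Markers of other cell types were mostly near the floor. Of 12 B cell markers 7 were under 1 FPKM, while Ighm, the immunoglobulin mu chain, was at 178 ± 48.7 FPKM with vehicle and 102 ± 19.2 with PGE2. Ighm missed the threshold (adjusted p = 0.2 with limma) and was lower with the replicate block (adjusted p = 0.01, with a range of 0.0042 to 0.49 over the alternatives). Of the 5 tested B cell markers 0 were called by limma, and 1, Ighm, was lower at an unadjusted p under 0.05, when adjusted over the list alone and with the block; the list median was 0.01, its mean -0.17 and its test pointed down (adjusted p = 0.52 with camera). The median was -0.19 without vehicle replicate 3 and 0.15 without PGE2 replicate 3. Of 15 myeloid and dendritic cell markers 13 were under 1 FPKM, with Lyz2 at 0.0989 ± 0.122 and 0.00933 ± 0.0162, and Cd68 was at 3.63 ± 1.64 and 3.56 ± 0.793. Of 10 NK and CD8 T cell markers 7 were under 1 FPKM; Nkg7 was at 53 ± 1.2 and 39.8 ± 1.34 FPKM, and was lower with the replicate block (adjusted p = 0.041, with a range of 0.005 to 0.25). Klrd1, of the same list, went the other way, from 1.46 ± 1.16 to 3.1 ± 1.22 FPKM (adjusted p = 0.38 with limma), and was higher with the replicate block. All 10 erythroid and platelet markers and 9 of 10 stromal and endothelial markers were under 1 FPKM, the exception being Pecam1 at 9.82 ± 0.777 and 11.4 ± 0.885.

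Libraries of a group correlated at 0.977 to 0.99 over the tested genes (Pearson, log2(FPKM + 1); genes are not independent replicates), and libraries of different groups at 0.971 to 0.985. The first principal component held 39.9% of the variance and set the number 3 libraries of both groups, at 17.09 and 25.32, apart from the other 4, at -15.97 to -3.55. The second held 28.3% and parted vehicle, at 6.16 to 20.96, from PGE2, at -13.68 to -10.48. The number 3 libraries had the lowest depth of each group, and in them TCR and NF-kB response genes lay below the other 2 libraries, by a median log2 difference of -0.31 with vehicle and -0.21 with PGE2. The cAMP list was lower there too, by -0.39 and -0.28, as was the tumour-infiltrating Treg list, by -0.39 and -0.22. Among others, the identity (-0.18 and -0.24), effector (-0.23 and -0.21) and ATF4 (-0.25 and -0.14) lists were also lower there. The cell cycle (0.26 and 0.18), oxidative phosphorylation (0.09 and 0.23) and cholesterol (0.34 and 0.08) lists were among those higher there. B cell markers were lower there by -0.48 and -0.42, with 4 of 5 lower in both groups, and Cd68 was at 1.74 and 2.64 FPKM in the number 3 libraries and at 3.99 to 4.59 in the other 4. Without both number 3 libraries 94 genes rose and 44 fell, an alternative chosen after the data were seen, and the median was 0.29 for the cAMP list and 0.17 for the tumour-infiltrating list. No measure of library composition reached the smallest p the design allows, 0.1 in an exact two-sided permutation test with 20 arrangements: p was 0.5 for depth, 0.3 for the mitochondrial share, 0.9 for the share of ribosomal protein genes, 0.2 for the share of the 10 most abundant genes and 0.5 for unannotated loci.

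Several named values are uncertain because the gene overlaps another tested gene and the files do not state whether counting used strand. Foxp3, Ptger2, Ptger4, Tgm2, Il12rb2, Atp1b1, Tnfrsf9 and Irf7 overlap a gene on the opposite strand, and Foxp3, Il2ra, Ctla4, Sys1, Lta, Atp5b, Fdps and Hspa8 one on the same strand.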

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

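The alternatives by coverage, assembled locus, library weights and without both number 3 libraries were chosen after the data were seen. All 98 called genes kept their sign under both scalings, both filters, both pseudocounts, the block and each library left out; with coverage 95 did, and with assembled loci 78 of 79 that could be tested. A pseudocount of 0.1, median-of-ratios scaling, the filter of 1 FPKM in 3 libraries and assembled loci gave counts within 1.5 times of 69 higher and 29 lower, and 96, 94 and 98 of the 98 genes, and 72 of those 79, stayed past the threshold. No filter gave 33 higher and 12 lower over 26484 genes, more than the 12113 of the reported test. A test against a fold of 1.5 gave 9 and 3, the replicate block 215 and 180, coverage 157 and 79, and library weights 1061 and 1100. The weights were 3.99 for vehicle replicate 2 and 4.75 for PGE2 replicate 2, against 0.3 to 0.73 for the others. The weighted counts therefore rest mostly on vehicle replicate 2 and PGE2 replicate 2. Scaling to totals left 16 lower, and leaving out both number 3 libraries gave 44 lower. With 1 library left out, 16 to 53 genes were higher and 4 to 16 lower, with fewer samples in each fit. For the other settings the cause was not tested. Of the lists, 8 were higher and 2 lower. With an estimated correlation 0 were higher and 0 lower (2 and 0 at an unadjusted p under 0.05, camera in limma), fry gave 4 higher, coverage gave 0 lower (2 at an unadjusted p under 0.05), leaving out both number 3 libraries gave 1 lower, and leaving out 1 library gave 5 to 7 higher and 0 to 1 lower. Both scalings and the filter kept all 10 lists. The block kept all 10 and added the PGE2 receptor and Th2 lists; of the genes named by the rule it changed the calls of Ptger4, Ighm and Nkg7, and of those named after their values were seen it changed the calls of Klrd1, Atic, Phlda3 and Bbc3.

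Among named genes, coverage turned Tmcc1 to 0.23, Zfp710 to 0.01 and Sys1 to 0.09, and assembled loci turned Zfp710 to 0.04 and Ptger2 to -0.52 on the log2 scale. The other reversals were of genes not called: library weights gave Pcna 0.01 and Cd68 -0.13, leaving out both number 3 libraries gave Cd68 -0.15, and leaving out 1 library gave Il4ra -0.05 to 0.21, Maf -0.23 to 0.09, Pcna -0.12 to 0.04 and Cd68 -0.31 to 0.21. The cause was not tested. Alternatives that need counts, DESeq2 and limma-voom, were not run, and the scaling and filter alternatives were run on FPKM. Depth limits genes near 1 FPKM most, where 3.996 to 5.446 gigabases of fragments leave little coverage.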

Other observations

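The gene groups in the next 2 paragraphs were put together after the called genes had been seen, so each was tested on its members that were not called, against random lists of uncalled genes, with the outcome set down before those values were read. The random lists were matched on level alone, so a percentile takes no account of members that move together and can overstate the evidence. Members that narrowly missed the threshold count as not called. The tests on Tmcc1, on Zfp710 and on the number 3 libraries were chosen after the result was seen. Transcripts for building ribosomes were lower with PGE2. Of 32 ribosome biogenesis genes 6 fell, among them Gnl3, nucleostemin, from 28.3 ± 1.43 to 17.9 ± 1.37 FPKM (SD, n = 3; log2 change -0.63, adjusted p = 0.031 with limma), and Grwd1, from 10.7 ± 0.373 to 6.69 ± 0.261; with the replicate block 19 fell. Of the 26 not called, 25 had a lower mean with PGE2, Fbl being the exception (log2 change 0.36 in FPKM, SE 0.43, and -0.4 in coverage, SE 0.14), and their median log2 change of -0.46 lay below all 10000 random lists matched on mean FPKM (percentile 0). Of 20 one-carbon and purine synthesis genes 4 fell. Shmt1 and Shmt2, which pass a carbon from serine to folate, fell by 0.61 and 0.59 on the log2 scale, Mthfd1 by 0.61 and Ahcy by 0.68; with the replicate block 5 fell, Atic with them. The 16 not called had a median of -0.21, at percentile 0.02 of the random lists, and 14 of them had a lower mean. Both directions held under either scaling, with medians over all members of -0.45 and -0.52 for ribosome biogenesis and -0.24 and -0.32 for one-carbon and purine genes. The calls rest on all 6 libraries: without any 1 of them 0 ribosome biogenesis genes fell by limma, with 27 to 29 lower at an unadjusted p under 0.05. Of the one-carbon and purine genes 1 fell without vehicle replicate 3 and 0 without any other library, with 9 to 11 lower at an unadjusted p under 0.05. With 1 library left out, the median of all members was -0.51 to -0.41 for ribosome biogenesis and -0.31 to -0.24 for one-carbon and purine genes, and that of the 16 was -0.13 without vehicle replicate 3.

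Targets of p53 were lower as a group, and the Gimap family, GTPases of lymphocytes encoded side by side, was higher. Of 20 p53 targets 3 fell: Ccng1 from 82.3 ± 3.02 to 53.9 ± 2.81 FPKM, Aen, and Zmat3 from 12.9 ± 0.69 to 8.53 ± 0.413. With the replicate block 5 fell, Phlda3 and Bbc3 with them. The 17 not called had a median of -0.32, below all 10000 random lists (percentile 0), although Sesn1, Fas, Btg2 and Plk2 among them had a higher mean. The other 13 had a lower mean, among them Cdkn1a (log2 change -0.27, adjusted p = 0.51 with limma) and Mdm2 (-0.06, adjusted p = 0.86 with limma). Of 8 Gimap genes 3 rose, Gimap4 from 288 ± 13.5 to 449 ± 28.1 FPKM, Gimap5 from 22.8 ± 1.32 to 36 ± 2.96 and Gimap7 from 45.1 ± 6.92 to 84.2 ± 6.77, and 6 rose with the replicate block. All 5 not called had a higher mean, with a median of 0.38 at percentile 99.98. Over all members, the medians of both scalings were -0.3 and -0.37 for p53 targets and 0.67 and 0.59 for Gimap genes. As members of a family, some Gimap genes may share reads, which was not tested. Coverage gave the 5 not called a median of 0.44. Without vehicle replicate 3, 2 p53 targets fell and 2 Gimap genes rose, and without PGE2 replicate 1, 1 p53 target fell. Without any of the other libraries 0 of either were called by limma, with 8 to 11 p53 targets lower, 1 higher and 7 Gimap genes higher at an unadjusted p under 0.05. All 4 groups were found and tested on the same libraries. Of other growth-related lists, cell cycle genes had a median of -0.06 and were not called (adjusted p = 0.79 with camera), with 0.05 without vehicle replicate 3. The glycolysis median was 0.24 (adjusted p = 1e-07 with camera, and 0.42 with an estimated correlation). Differences between lists were not tested.

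The 98 calls were set against other splits of the 6 libraries. Of the 10 splits into 3 and 3, 1, the real one, gave as many genes; the highest of the others gave 3. Of the 4 splits that part all 3 replicate numbers, the real split gave 98 genes and the highest other 3, or 395 and 1 with the block, while splits that part a single number gave at most 1. With 10 splits no share under 0.05 can be had. Each of the other splits mixes vehicle and PGE2 libraries, so any PGE2 effect adds to the spread within groups and lowers the count. Those counts are therefore not what chance alone would give.

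Tmcc1 fell by 3.55 and Zfp710 by 1.71 in FPKM. Less RNA over the whole gene is argued against: the log2 change of coverage was 0.23 for Tmcc1 and 0.01 for Zfp710, and even minus 2 standard errors it was -0.27 and -0.19. A candidate explanation is that reads of like total number were assigned to other transcripts of the locus, since FPKM depends on the transcripts to which reads are assigned and coverage here does not show the fall. Whether such a shift is a change of transcript use or of the estimate stays open, as values per transcript were not used here.

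The number 3 libraries were low in TCR and NF-kB response genes in both groups, by a median log2 difference of -0.26 from the other 4 libraries, and B cell markers were lower there by -0.48 with vehicle and -0.42 with PGE2. The prediction set for lower depth was that genes of like level are as low, but the list lay below all 10000 random lists of the same mean FPKM (percentile 0). FPKM is already scaled to library size, so lower depth need not lower values. Random lists may then show no fall whether or not depth had a part. The list was chosen after it was seen to be low there, and random lists take no account of members that move together. The test therefore does not settle whether depth had a part. More Foxp3-negative activated CD4 T cells in these libraries stays open, and the sort on the reporter should remove such cells. Foxp3 was lowest there, at 75.4 FPKM with vehicle and 91.1 with PGE2, but the cytokine list of conventional CD4 T cells, whose most abundant genes Lta and Ltb stood at 595 and 579 FPKM with vehicle, lay at percentile 71.45, with a median difference of 0.09; all 6 tested members are expressed in the sorted cells, and Tnf and Cd40lg are also in the TCR and NF-kB list. A different share of B cells or myeloid cells was not tested, nor was any biological explanation, since the labels give the numbers no meaning.

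Outside the annotated genes, 337 assembled loci were present in all 6 libraries. By limma 0 were higher and 0 lower with PGE2 (smallest adjusted p = 0.13), and 28 had an unadjusted p under 0.05.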
